A study of Mus musculus with 2 samples.

How the data were processed

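MicroRNA sequencing libraries of total RNA below 30 nucleotides were analysed from the adrenal glands of 2 female mice aged 25 days, 1 library per animal. Per the labels, the libraries are biological replicates 1 and 2 of 1 group and carry the numbers of separate animals, with the same donor identifier for both. Per the labels, reads were mapped to mm10, and the text deposited with each table names the GENCODE M21 gene annotation. The authors deposited 1 table per library of raw read counts per miRNA gene, with no normalization and no pooling. The aligner, the counting tool, the trimming and their versions are not given in the sources used here. The tables have no header and hold 3 columns of counts. Their layout is that of a gene counter that gives an unstranded column followed by 2 stranded columns.

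The stranded column with the larger total in both libraries was taken as the reads on the strand of the gene, and it gave the main values. The meaning of the columns was inferred from this layout and from the values. The 2 stranded columns summed to the unstranded column except at 56 genes in library 1 and 62 in library 2. All 2202 gene identifiers were found in GENCODE M21, which gave symbols, coordinates and overlapping genes.

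The rows that name no gene were left out of library sizes and tests. Unmapped reads made up 33.8% of library 1 and 27.8% of library 2, reads mapped to several places 28.4% and 27.5%, and reads outside miRNA genes 9.57% and 9.53%. Reads ambiguous between genes made up 3.84% and 7.49% in the unstranded column. Reads mapped to several places are in no gene count, so miRNA genes with identical mature copies were undercounted. A stretch of 20 bases shared with another miRNA gene position, on either strand, was found for 1107 genes, whose counts are uncertain. The search covered miRNA genes only, and copies elsewhere in the genome were not searched. An overlapping miRNA gene on the other strand was annotated for 64 genes, and 1179 genes lie in another gene on the same strand. The animals carry a CAST chromosome set, and reads with CAST variants can map less well to the reference in both libraries.

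The counts were analysed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0. Levels were expressed as CPM, with the reads on the strand of miRNA genes as the library size. With 1 group there was no coefficient for a quasi-likelihood test. Each gene with 10 or more reads summed was tested with a two-sided exact binomial test, conditional on the sum, with edgeR's TMM effective library sizes. The p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Log2 ratios are library 2 over library 1, with 0.5 read added to each count and 95% intervals from counting error. A gene was called detected with 10 or more reads in each library. The biological coefficient of variation is edgeR's common value under an intercept-only design. Correlations used log2 of CPM plus 1. Shares have 95% Wilson intervals.

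The choices of tests, alternatives, named genes and 21 gene lists were made before the data were examined. Named genes are the 25 with the highest mean CPM and the 10 with the largest ratio between libraries among genes with an adjusted p under 0.05 and 200 or more reads. Named as well are up to 4 most abundant members of each list and up to 3 genes with the most reads on the other strand, with 10 or more in each library. Mir503, Mir16-1, the genes on whose other strand reads lay without a partner, and the neighbouring genes of the closing part outside this rule were named after their values were seen.

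The lists are the let-7 family, the Dlk1-Dio3 cluster, other imprinted loci, the Sfmbt2 cluster, the miR-17-92 cluster with its paralogs, the miR-30 and miR-29 families and the Hox clusters. Further lists are miRNAs studied in adrenal cortex or steroidogenic cells, neuroendocrine and neural, endothelium, smooth muscle and fibroblast, and erythroid cells and platelets. The remaining lists are leukocytes, epithelium and kidney, liver, striated muscle, adipose tissue, gonad, exocrine pancreas, and entries of uncertain origin.

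For each list with 3 or more detected genes, the median log2 ratio was set against 10000 random lists of the same size, drawn within 10 bins of mean level. The random lists were at first drawn without the list's own genes. In simulated unchanged lists of 10 genes among 337, that form gave p under 0.05 in 21 of 300 lists and the form with all genes in 17 of 300. The form with all genes was used, a change made after the values were seen. In it a list and its random lists are exchangeable only if genes vary independently, as they did in the simulation. Genes of the same primary transcript, such as Mir451a and Mir144, may not, so the p can be too small. The earlier form gave the same 4 lists, with adjusted p from 0.0034 to 0.0102. Neighbouring genes on the same strand within 10 kb were compared with 10000 random re-pairings, leaving out pairs of a gene with itself, a step that was also added after the values were seen.

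The binomial test was tried on data simulated from the real means and library sizes, with counting error only and no spread between animals. It called 62.9% of genes changed 1.5-fold, 75.8% of genes changed 2-fold and 100.0% of genes changed 4-fold. It called 1 of 218 unchanged genes. The scaling in the simulation was the median ratio of abundant genes known to be unchanged, in place of TMM. These rates leave out error of the scaling and do not hold for libraries with a spread beyond counting error, as found here. Simulated coefficients of variation of 0.2, 0.4 and 0.6 were recovered as 0.208, 0.386 and 0.592. Alternatives covered the scaling (library size, DESeq2 size factors), the filters, the pseudocount, the unstranded column, the denominators of shares, the distance between neighbours and leaving out each library. Added after the data were seen were a fold limit of 2, the spread and the shares without Mir451a and Mir144, the neuroendocrine list without Mir182, Mir183 and Mir96, pairs with gene values shuffled, and list medians after a lowess correction of the log2 ratios for the GC content of the hairpin.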

Results

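Small RNA of the adrenal gland was sequenced from 2 female mice aged 25 days. The animals were of the strain B6CASTF1/J, a first-generation hybrid of a laboratory strain and the wild-derived CAST strain. The adrenal gland has an outer cortex, which makes steroid hormones, and an inner medulla of neural crest derived chromaffin cells, which release catecholamines. The assay was microRNA sequencing of a total RNA fraction below 30 nucleotides. The labels gave 1 group of 2 biological replicates and no contrast between groups. They number the glands as those of separate animals but give both samples the same donor identifier, so the libraries compare animals only if those numbers hold. With 1 library per animal, each SD and the variation between libraries also hold differences of dissection, library preparation and sequencing, which cannot be told apart from animals. The comparisons below therefore describe the miRNA profile of the gland and how far the 2 libraries, one per animal, differed. Library 1 held 7938596 reads, of which 2244073 (28.3%) were counted on the strand of an annotated miRNA gene. Library 2 held 11132685 reads, of which 3912280 (35.1%) were counted so. Levels are given as normalised read counts (CPM), the reads of a gene scaled to the sum of such reads in its library. Reads mapped to several places, 28.4% of library 1 and 27.5% of library 2, are in no gene count. The ranks and shares below thus understate miRNA genes with identical copies. Intervals cover counting error only and no spread between animals. They can be too narrow even for counting error, since PCR reads without molecular identifiers are not independent molecules.

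By the mean of both libraries, the most abundant miRNA gene was Mirlet7g, a member of the let-7 family, which represses growth and stem cell genes in differentiated tissue, with 105130 ± 7328 CPM (SD, n = 2). Mir126a, which lies in the endothelial gene Egfl7 and is a marker of blood vessels, followed with 87385 ± 47549 CPM (SD, n = 2). In library 2 Mir126a was above Mirlet7g, with 121010 against 99953 CPM. Mirlet7b had 64191 ± 25471 CPM, Mir10a of the Hoxb cluster 56744 ± 13735 CPM and Mirlet7i 52737 ± 1198 CPM (SD, n = 2). Mir378a, which lies in an intron of the mitochondrial regulator gene Ppargc1b, had 43969 ± 6134 CPM (SD, n = 2). Mir375, a miRNA of endocrine and neuroendocrine cells, had 37067 ± 716 CPM, and Mir143, a miRNA of smooth muscle and fibroblasts, had 33923 ± 9376 CPM (SD, n = 2). Mir23b, Mir22, Mirlet7d, Mir23a, Mir322, Mir26b and Mir139 came next, from 30697 down to 21446 CPM. Mir21a, Mir10b, Mir99a, Mir451a, Mir127, Mir30d, Mir30a, Mirlet7e, Mir652 and Mir30e completed the 25 most abundant genes, from 20744 down to 8815 CPM. The place of Mir451a among them rests on library 2, with 24242 CPM there and 480 CPM in library 1. Among the 25, Mir378a, Mir23b and Mir23a share a stretch of 20 bases with another miRNA gene position, so their counts are uncertain. Mirlet7g alone took 10.5 ± 0.73% of the miRNA reads, the 10 most abundant genes 54.0 ± 0.39% and the 25 most abundant genes 79.2 ± 0.76% (SD, n = 2). With at least 10 reads in each library, 337 of the 2202 annotated miRNA genes were detected.

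In mm10 coordinates, Mirlet7g (ENSMUSG00000065440.1) spans bases 106178840 to 106178927 of chromosome 9, in an intron of Wdr82. Mir126a (ENSMUSG00000065540.1) spans bases 26591357 to 26591429 of chromosome 2, overlapping an annotated exon of an Egfl7 transcript. Mirlet7b (ENSMUSG00000065564.1) spans bases 85707319 to 85707403 of chromosome 15, in an exon of the long noncoding RNA gene Lncppara. Mir10a (ENSMUSG00000065519.1) spans bases 96317165 to 96317274 of chromosome 11, and Mir375 (ENSMUSG00000065616.3) spans bases 74900658 to 74900721 of chromosome 1. Neither Mir10a nor Mir375 lies within an annotated gene on its own strand. Mir378a (ENSMUSG00000105200.1) spans bases 61397835 to 61397900 of chromosome 18. Mir451a (ENSMUSG00000070065.1) spans bases 78073170 to 78073241 of chromosome 11 and Mir144 (ENSMUSG00000065401.1) spans bases 78073005 to 78073070 of it, with no host gene for either. Mir122 (ENSMUSG00000065402.1) spans bases 65248861 to 65248926 of chromosome 18, in an exon of the long noncoding RNA gene AC157910.3. Mir22 (ENSMUSG00000065529.1) spans bases 75463716 to 75463810 of chromosome 11, overlapping an annotated exon of Tlcd2.

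**Figure D1:**
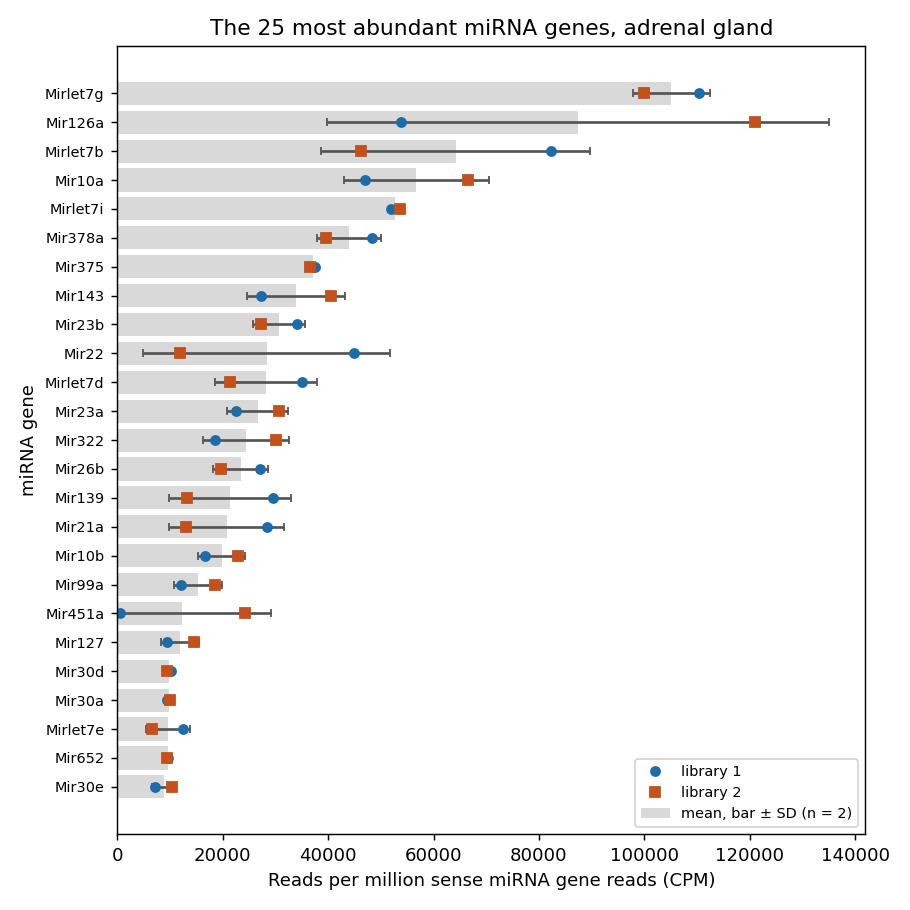
Levels of the 25 most abundant miRNA genes as normalised read counts (CPM). Bars show the mean and error bars the SD of 2 libraries, with library 1 as circles and library 2 as squares. Mirlet7g has the highest mean with 105130 CPM, and the points of Mir126a, Mir22 and Mir451a lie far apart.

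The question of which gene groups made up the adrenal profile was put to 21 lists of miRNA genes. The let-7 family held 27.4 ± 4.83% of the miRNA reads, and miRNAs studied in adrenal cortex or steroidogenic cells held 9.26 ± 1.11% (SD, n = 2). Of the latter list, 25 of 26 annotated genes were detected, led by Mir375, Mir21a with 20744 ± 10949 CPM and Mir10b with 19789 ± 4403 CPM (SD, n = 2). The neuroendocrine and neural list held 4.43 ± 0.0919% of the reads, with 19 of 28 genes detected (SD, n = 2). Most of these reads came from Mir375, which is in both lists, and Mir7b followed with 4732 ± 1147 CPM (SD, n = 2). Mir182 had 652 ± 129 CPM and Mir137 608 ± 264 CPM (SD, n = 2). A stretch of 20 bases is shared with another miRNA gene position by 6 of 12 annotated let-7 genes, 9 of 26 of the adrenal cortex list and 18 of 28 of the neuroendocrine list. The counts of these genes are uncertain.

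Of the imprinted Dlk1-Dio3 cluster on chromosome 12, expressed from the maternal chromosome, 49 of 59 genes were detected, and they held 4.83 ± 0.617% of the reads (SD, n = 2). Its most abundant members were Mir127 with 11948 ± 3607 CPM, Mir411 with 8368 ± 2973 CPM and Mir379 with 7196 ± 898 CPM (SD, n = 2). Mir411 shares a stretch of 20 bases with another miRNA gene position, so its count is uncertain. The other imprinted loci held 0.997 ± 0.129%, led by Mir335 with 8253 ± 1994 CPM (SD, n = 2). The genes of the Hox clusters held 7.84 ± 1.75%, the miR-30 family 2.91 ± 0.223%, the miR-17-92 cluster with its paralogs 1.14 ± 0.187% and the miR-29 family 0.468 ± 0.0184% (SD, n = 2). The imprinted Sfmbt2 cluster held 0.094 ± 0.0134% (SD, n = 2). Of its 45 genes, 43 share a stretch of 20 bases with another miRNA gene position, and how many of their reads were left out as mapped to several places was not measured.

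Markers of other cell types were present at unequal levels. The endothelial list, which is nearly all Mir126a, held 8.74 ± 4.75% of the reads and the smooth muscle and fibroblast list 3.54 ± 0.912% (SD, n = 2). The adipose tissue list held 4.61 ± 0.686%, most of it Mir378a, which other tissues rich in mitochondria also express (SD, n = 2). The erythroid list held 1.32 ± 1.77%, the leukocyte list 0.187 ± 0.0364% and the liver list, which is Mir122, 0.284 ± 0.332% (SD, n = 2). The list of epithelium and kidney held 0.123 ± 0.0432% and that of gonad 0.16 ± 0.00124%, of which Mir34c had 1392 ± 17.4 CPM (SD, n = 2). Entries of uncertain origin held 0.153 ± 0.00684%, led by Mir1839 (SD, n = 2). The striated muscle list had 16 and 14 reads and the exocrine pancreas list 4 and 5 reads in libraries 1 and 2, with no gene of either list detected. Of the 10 annotated striated muscle genes, 6 share a stretch of 20 bases with another miRNA gene position. Their reads can be missing as mapped to several places, so the low count does not show that muscle was absent.

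The largest ratio between the libraries among genes with 200 or more reads was that of Mir451a. This gene, which drives red blood cell maturation, was 53.5-fold higher in library 2 than in library 1, with 94842 reads against 1078. Mir144, its neighbour in the same primary transcript, was 10.1-fold higher in library 2, and Mir185 was 14.0-fold higher. Mir153, which lies in an intron of the neuroendocrine gene Ptprn2, was 3.42-fold higher in library 2. Higher in library 1 were Mir122, the main miRNA of hepatocytes, by 9.96-fold, the neutrophil miRNA Mir223 by 4.34-fold and Mir22 by 3.58-fold.

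Higher in library 1 were also mmu-mir-3535, in an exon of the nucleolin gene Ncl, by 3.88-fold and Mir6538 by 3.31-fold. Mir26a-2 was 32.6-fold higher in library 1, with 1540 reads against 77, and shares a stretch of 20 bases with Mir26a-1, so its count is uncertain. Among the abundant genes, Mir126a was 2.39-fold higher in library 2. Mir139 was 2.11-fold and Mir21a 2.06-fold higher in library 1. Mirlet7g (log2 ratio of library 2 over library 1 -0.06) and Mir375 (log2 ratio 0.05) were nearly level. The sign for Mirlet7g turned with DESeq2 size factors and that for Mir375 with scaling by library size.

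In the exact binomial test of each gene, which compares these 2 libraries and not conditions, 240 of 411 tested genes passed an adjusted p of 0.05. Of these, 121 were higher in library 2 and 119 in library 1. With a fold of 1.5 or more required as well, 129 genes remained, 62 higher in library 2 (48.1%) and 67 in library 1. The split moved with the settings. The share higher in library 2 was 38.5% with scaling by library size alone and 62.4% with DESeq2 size factors. It was 66.4% with no filter on low counts, which changed both the genes tested, 751 in place of 411, and the TMM scaling. The DESeq2 size factors shifted the log2 ratios of all genes by 0.13 and leaving out the filter by 0.17, so changes are relative to the main scaling. The biological coefficient of variation between the libraries, estimated with edgeR, was 0.382 over 337 genes. Across the same 337 genes, which are not independent replicates, the log2 levels had a Pearson r of 0.97 and a Spearman rho of 0.967.

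**Figure D2:**
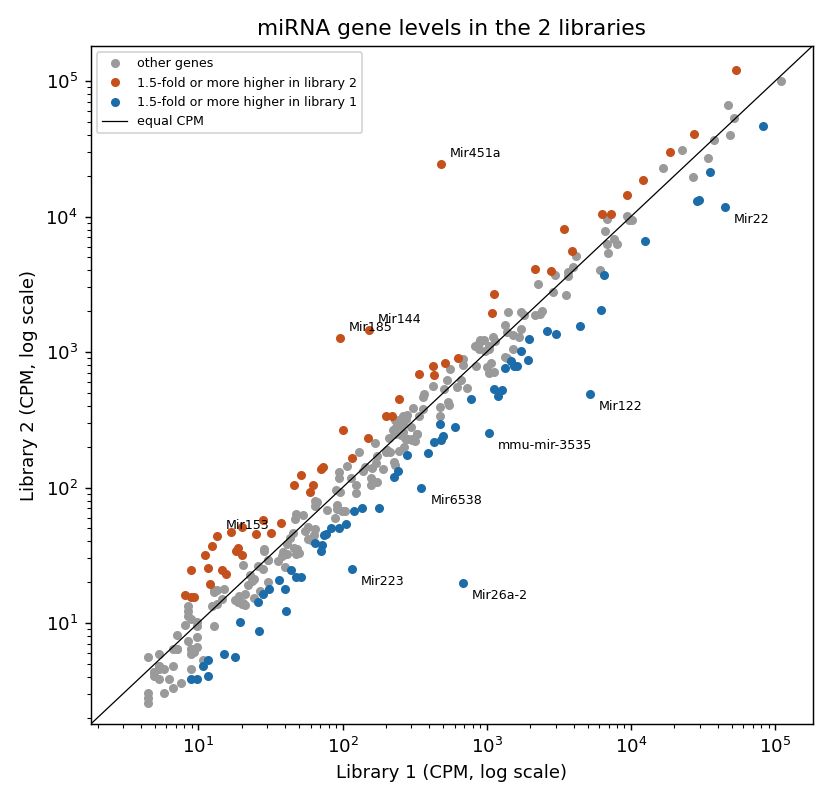
Level of each of the 337 detected miRNA genes in library 1 and library 2, in CPM on log axes, with the line of equal CPM. Coloured points passed the exact binomial test and a fold of 1.5 after TMM scaling, and the named points, such as Mir451a and Mir122, are the 10 with the largest such ratios among genes with 200 or more reads.

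The erythroid list held 0.068% of the reads in library 1 and 2.57% in library 2. Of its 3 detected genes, Mir451a and Mir144 were higher in library 2, and Mir486, which shares stretches with 2 other gene positions, was 2.04-fold higher in library 1. The let-7 family took 30.8% of the reads in library 1 and 24.0% in library 2, with a median log2 ratio of -0.54. Of its 12 genes, 6 were higher in library 1 by 1.5-fold or more, among them Mirlet7b (1.68-fold) and Mirlet7e (1.78-fold), and none was higher in library 2. Of the 25 detected genes studied in adrenal cortex or steroidogenic cells, 9 were higher in library 1 and 4 in library 2 by 1.5-fold or more, with a median log2 ratio of -0.48 and shares of 10.04% in library 1 and 8.48% in library 2. Mir21a and Mir125a (log2 ratio -1.53) were among those higher in library 1. Of the 19 detected neuroendocrine and neural genes, 8 were higher in library 2 and 1 in library 1, with a median log2 ratio of 0.49. The share of the list was 4.36% in library 1 and 4.49% in library 2, most of it from Mir375, which was nearly level. Mir137 (log2 ratio 1.00) and Mir7b (log2 ratio 0.59) were higher in library 2.

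Each of these 4 lists stood apart from 10000 random lists matched on level, with an adjusted permutation p of 0.0433 over 17 lists tested. The test takes genes as independent units, which neighbours in the same transcript may not be. With 100 or more reads required in each library, the adjusted permutation p was 0.0615 for the let-7 family, 0.0615 for the adrenal cortex list and 0.498 for the neuroendocrine list. The erythroid list, of 3 detected genes with Mir451a and Mir144 in 1 transcript, could not be tested there, since Mir486 had 86 reads in library 2. After a correction of the log2 ratios for GC content it was 0.117 for the adrenal cortex list. Adjusted over the list alone, 10 let-7 genes, 20 of the adrenal cortex list, 14 of the neuroendocrine list and 3 erythroid genes passed the binomial test, which are the counts over all genes tested as well.

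The other 13 tested lists did not stand apart from random lists, with adjusted permutation p from 0.424 to 1. The Dlk1-Dio3 cluster had a median log2 ratio of -0.08, with 7 genes higher in library 2, 7 in library 1 and 35 not called at 1.5-fold. The leukocyte genes went both ways. Mir142 was higher in library 2 (log2 ratio 0.85), Mir342 (log2 ratio -0.48), Mir150 (log2 ratio -0.92) and Mir223 were higher in library 1, and Mir155 had a log2 ratio of 0.06 with a 95% interval from -0.07 to 0.19. The endothelial share, that of Mir126a, was 5.38% in library 1 and 12.1% in library 2, and the smooth muscle share was 2.89% and 4.18%. In the latter list Mir143 was higher in library 2 (log2 ratio 0.66) and Mir214 in library 1 (log2 ratio -0.71).

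**Figure D3:**
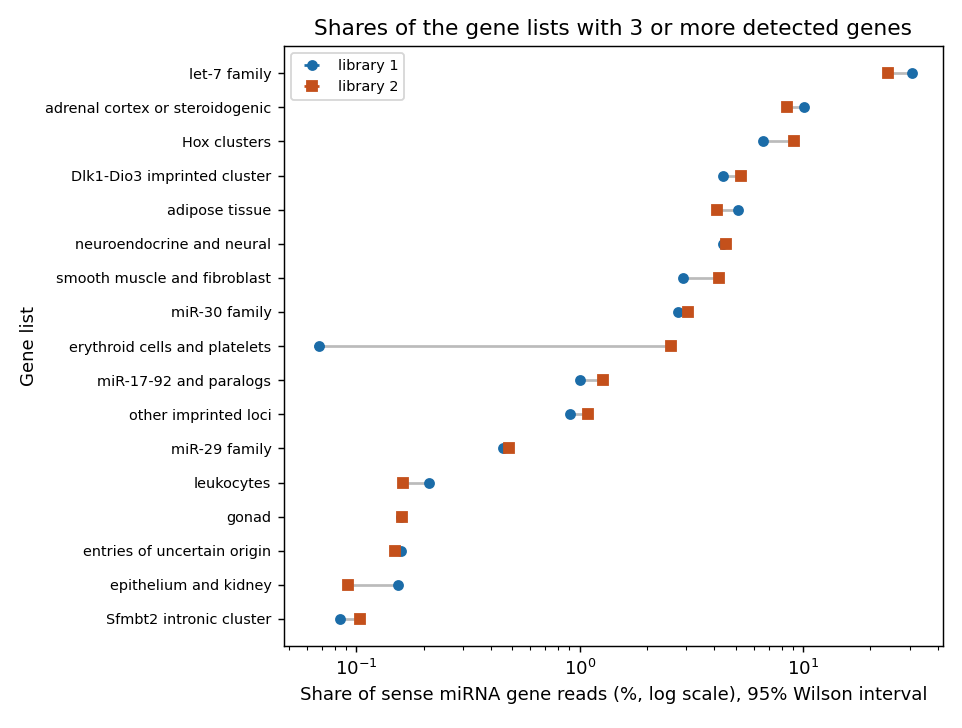
Share of sense miRNA gene reads held by each gene list with 3 or more detected genes, in percent on a log axis, with 95% Wilson intervals smaller than most symbols. Circles are library 1 and squares library 2, and the erythroid list spans the widest gap, from 0.068% to 2.57%.

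Neighbouring miRNA genes, which can share a primary transcript, were compared to see how close their levels lay. In the 108 pairs of detected genes on the same strand within 10 kb, the median difference was 2.12 on the log2 CPM scale. Random re-pairings of the same 151 genes gave a median of 2.90 (one-sided permutation test, adjusted p = 0.005). With 100 or more reads in each library the difference was 1.93 against 2.32 in re-pairings and no longer passed (adjusted permutation p = 0.125). Members of a pair still differed widely. Mir143 had 51.4 times the level of Mir145a in library 2 and 32.2 times in library 1. Mir322 had 122 times the level of Mir503 in library 2 and 56.2 times in library 1. The log2 ratio between libraries differed by a median of 0.51 within pairs and 0.61 in random re-pairings (one-sided permutation test, adjusted p = 0.0504), which did not pass the threshold. It passed within 3 kb (adjusted permutation p = 0.0288), within 50 kb (0.0133) and with gene values shuffled over the same pairs (0.0308).

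The strand of the reads decided several of the abundant genes. Mir126a, Mir378a, Mir451a, Mirlet7e and Mir30e each overlap an annotated miRNA gene on the other strand. In the unstranded counts their reads were set aside as ambiguous, so that Mir126a had 3 and 10 reads there in place of 120647 and 473413. Of the reads opposite to a miRNA gene, 99.93% in library 1 and 99.97% in library 2 lay at genes with such a partner. With both libraries summed, the largest such counts were at Mir126b, Gm25301 and Mir451b, opposite Mir126a, Mir378a and Mir451a.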

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

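All reads described here lie outside the main counts, and no test was run on them. Reads on the strand opposite to the gene, with no miRNA gene annotated there, exceeded the 3 reads that a count of 0 allows in both libraries at 4 genes. Mir203 had 144 such reads in library 1 and 188 in library 2, which were 4.60% (95% Wilson interval 3.92 to 5.40%) and 5.93% (5.16 to 6.80%) of its reads on both strands. Mir708 had 12 and 20, Mirlet7b 12 and 8, and Mir130a 4 and 8.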

How the results depend on the processing

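The tests with a fold limit of 2, without Mir451a and Mir144, with shuffled gene values and with a GC correction were chosen after the data were seen. No paired analysis was possible because there is 1 group. Of the main results, 198 alternative values stayed within the limits set for their kind. Tests of lists and pairs had to keep their side of the threshold, and shares to move by less than their SD. Counts of genes and the coefficient of variation had to stay within 1.5-fold, and correlations within 0.05. These limits are wide, so that 429 detected genes with a minimum of 3 reads, against 337, lay within them. Of the others, 22 moved further, 5 lost the threshold and 3 gained it. Part of the 198 could not come out otherwise. With 2 libraries, the share in a single library always lies within the SD of the mean. A change of scaling shifts all log2 ratios equally and leaves the list permutation p unchanged. Of the 80 medians of lists that kept their side, 12 changed sign, none of a list that stood apart. The calls at 1.5-fold were 65 with a fold limit of 2. Without the 10 most abundant genes 97.6% of the calls among the other genes remained. In the unstranded counts, which drop genes with an overlapping partner, Mirlet7g held 12.7% and the top 25 genes 76.3%. Shares there were 5.50% for Dlk1-Dio3, 1.22% for other imprinted loci, 0.115% for Sfmbt2, 1.39% for miR-17-92, 11.1% for adrenal cortex and 5.34% for neuroendocrine. They were 0.00024% for endothelium, 0.251% for adipose tissue, 0.195% for gonad, 0.186% for uncertain origin, 2.46% for miR-30 and 0.568% for miR-29. The erythroid share fell from 1.32% to 0.101% in the unstranded counts. In the main counts without Mir451a and Mir144 it was 0.0035%. Both moves were smaller than its SD of 1.77. The most abundant gene, Mirlet7g, was also left out of all counts, and so of both the denominator and its own family. Shares were then 18.9% for let-7 without Mirlet7g, 4.95% for neuroendocrine, 0.179% for gonad, 0.172% for uncertain origin, 3.25% for miR-30 and 0.523% for miR-29. The gonad share without Mir451a and Mir144 was 0.162%. With 100 or more reads in each library, fewer genes were tested, and the list medians were -0.54 for let-7, -0.53 for adrenal cortex and 0.49 for neuroendocrine, no longer past the threshold, and the erythroid list kept too few genes for a test. The adrenal cortex median after the GC correction was -0.42, also no longer past it. With 100 or more reads, neighbouring pairs differed by 1.93 on the log2 CPM scale, also no longer past it. The pair difference of log2 ratios passed it within 3 kb (0.50), within 50 kb (0.49) and with shuffled values (0.51), and the cause was not tested. Ratios near 0 turned sign with the scaling, to 0.075 for Mirlet7g, 0.11 for Mir30d and 0.12 for Mir145a with DESeq2 size factors, and to -0.039 for Mir375, -0.028 for Mir652 and -0.00017 for Mir29a with library size. With single libraries, detected genes ranged from 341 to 370, the Mirlet7g share from 9.995 to 11.03%, the top 25 from 78.7 to 79.7%, the erythroid share from 0.068 to 2.57% and the liver share from 0.049 to 0.518%. Genes with few reads limit the precision. Counts were simulated with counting error only and scaled on genes known to be unchanged. In them 1.5-fold changes were called for 89.2% of genes with 200 or more reads and for 62.9% of all.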

Other observations

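Chosen after the results were seen were the tests of neighbouring genes below, of the red blood cell list, white blood cells, blood plasma, medulla and call rates in genes that share a stretch. Neighbouring miRNA genes ranged from near-equal to very unequal levels. Mir181d had 0.981 times the level of Mir181c in library 1 and 1.19 times in library 2. Mir379 had 1.05 and 0.748 times the level of Mir411, whose count is uncertain. Mir127 had 35.6 times the level of Mir434, 1591 bases away in the Dlk1-Dio3 cluster, in library 1 and 48.2 times in library 2. Mir431 had 0.709 times the level of Mir433 in each library, at 1428 ± 137 and 2015 ± 194 CPM (SD, n = 2). In the miR-34 cluster of chromosome 9, Mir34c had 30.7 times the level of Mir34b in library 1 and 30.5 times in library 2. In the X-linked cluster, Mir351 had 7.25 and 8.13 times the level of Mir503. Mir451a had 3.15 times the level of its neighbour Mir144 in library 1 and 16.7 times in library 2, the largest shift among the pairs given here. In the cluster of Mir99b, Mirlet7e and Mir125a on chromosome 17, Mirlet7e had 3.64 times the level of Mir99b in library 1 and 0.818 times in library 2.

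The red blood cell miRNA genes Mir451a and Mir144 were higher in library 2, while Mir486 was higher in library 1. Mir486 had 107 and 86 reads and shares stretches with 2 other gene positions, so its ratio is uncertain. An effect on the reads of Mir451a alone, as the whole cause, is argued against by Mir144, with a log2 ratio of 3.33 (95% interval 3.18 to 3.49). A part of the Mir451a ratio was not shared by Mir144, since Mir451a had 3.15 times its level in library 1 and 16.7 times in library 2. More red blood cells left in the tissue of animal 2 is a candidate explanation that stays open. Of 16 other genes abundant in red blood cells, the median log2 ratio was 0.49. Among them, Mir16-1 had 2508 of 2244073 miRNA reads in library 1 and 10510 of 3912280 in library 2. But 5 of the 16, Mir16-1 included, had been seen before, and 11 are in other lists too. The 11 not seen had a median of 0.33 at percentile 89.3 of random lists (two-sided permutation p = 0.213). White blood cells arriving with them stay open too, since the leukocyte median of -0.48, the value of Mir342, came from members that went both ways, with Mir342, Mir150 and Mir223 lower in library 2, Mir155 near 0 and Mir142 higher.

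Many miRNA genes differed between the 2 libraries. After a correction for GC content of the hairpin, 101 of the 118 calls at 1.5-fold among the 337 detected genes (85.6%) remained. This argues against it as the whole cause. A partial effect is not excluded, since the log2 ratio fell with GC content (Spearman rho -0.24) and the fitted trend spanned 0.90 log2 units. GC content of the sequenced mature miRNAs was not measured, so the test does not cover it. For the adrenal cortex list GC content of the hairpin stays open (median log2 ratio -0.48 before and -0.42 after). Its adjusted permutation p was then 0.117, the largest of the let-7, adrenal cortex and neuroendocrine lists. Reads lost to near-identical copies stay open, since 70.5% of the calls were in genes that share no stretch, but these are 317 of the 411 tested genes, of which 28.7% were called, against 40.4% of 94 sharing genes (two-sided Fisher's exact p = 0.0424). More medulla in the tissue of animal 2 stays open for the neuroendocrine list, whose median was 0.49 with 100 or more reads as well (adjusted permutation p = 0.498, the largest of 3 settings), while its share (4.36% and 4.49%) and Mir375 (log2 ratio 0.05) were nearly level. Differences between individual animals were not tested apart from those of dissection.

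Mir122 was higher in library 1. Liver tissue in the dissected gland is a possible explanation that stays open, since Mir192, Mir194-1 and Mir194-2 had a median log2 ratio of -0.27, that of Mir192 (95% interval -0.64 to 0.09), with Mir194-2 at -0.47 (-0.80 to -0.14) and Mir194-1 at 0.38 (-1.45 to 2.21). Blood plasma in the tissue stays open as well, since the blood miRNA genes went both ways. Mir451a, with a log2 ratio of 5.74, was higher in library 2. Higher in library 1 were Mir223 (-2.12), Mir150 (-0.92) and Mir486 (-1.03), whose count is uncertain. For all 3 patterns the labels give no group that would supply a biological explanation, and none was tested.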
